A study of Homo sapiens with 8 samples.

How the data were processed

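RNA sequencing libraries were made from B cells sorted by flow cytometry from 4 human tonsils. Per the labels' protocols, total RNA came from 100000 sorted cells per sample with a phenol reagent and column kit, was treated with DNase, and was used where its integrity number was above 7. Ribosomal RNA was depleted and libraries were made with a stranded total RNA kit that uses template switching, per the labels' protocols. Per the submitters' processing notes, which give no roles, Trim Galore, a read trimmer, HISAT2, an aligner, and the human build hg38 were used. Their versions, the counting tool, the annotation, and the treatment of strand and of reads with several positions are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene, 67130 genes in 8 columns, with identifiers that pair an Ensembl gene with a symbol. The deposited counts were taken as raw counts: all values are whole, none is below 0, and column totals run from 32143496 to 92812999. No column was left unused. Because the strand setting is not given, overlapping and antisense genes may share counts, and because the treatment of reads with several positions is not given, near-identical paralogs (IgG constant genes, 5.8S ribosomal RNA copies, HSPA1A and HSPA1B, histone genes) are uncertain one by one.

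Samples were grouped by their titles into GC and MZ B cells, and the tonsil code in the title numbers the replicates, called tonsils 1 to 4 in ascending order of code. Table columns were matched by the tonsil code and the population in the column name. The 4 columns named for GC matched the GC titles. The other 4 are named for effector B cells, a word in no label, and were matched to the MZ sample with the same code, the only other sample of that tonsil. Identifiers were looked up in GENCODE release 29 on the same build, which held 58453 of them; the other 8677 carried 0.07% of all counts. A symbol was shared by 8156 rows, and among these the primary-assembly identifier, then the larger total, kept the plain symbol.

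The main test was edgeR 4.0.16 (quasi-likelihood, robust estimation, in R 4.3.3) on the deposited counts, after edgeR's default expression filter by group, which left 20192 genes, and TMM normalization, with population as the only term. Calls were made at a Benjamini-Hochberg adjusted p below 0.05, and a 2-fold threshold was applied for 1 count. Standard errors of log2 fold changes were derived from the test statistic, and CPM values use TMM-adjusted library sizes. The common biological coefficient of variation was 0.42. A set of 30 gene lists was fixed and tested by camera with a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. None of the 17 lists called with the preset correlation held with the estimated correlation. Many genes are held by more than 1 list. Shares of immunoglobulin genes were compared with exact two-sided permutation tests in SciPy 1.17.1 (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3), where 4 against 4 cannot go below p = 0.029, and figures were drawn with matplotlib 3.10.9. Genes on the Y chromosome entered the fit but were not written out gene by gene.

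Named genes followed a rule fixed before the data were examined, as were the lists, tests and most alternatives. Part 1 took the 15 genes per direction with the largest log2 fold change among those called, with a mean log2 CPM of at least 3 and the same direction in all tonsils. It left out immunoglobulin and T cell receptor segments, HLA genes, Y-linked genes and XIST, and identifiers that are clone-based, antisense, mitochondrial or belong to certain noncoding RNA series. Part 2 took the 4 members of each list with the smallest p, of which the text names some, and part 3 was a fixed set of 20 B cell genes. Some genes that the rule takes are not reported here. Genes outside the rule are named only to say which members of a list belong to T cells, and in the closing section, where they were chosen after their values were seen.

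Samples with the same tonsil code were checked for pairing by correlating their deviations from the population means over all tested genes. The GC and MZ libraries of tonsils 1 to 4 correlated at 0.24, 0.25, 0.22 and 0.19, and no pair of libraries from different tonsils exceeded 0.06, so the codes pair the samples. A fit with tonsil as a block was run as an alternative beside the unblocked one. Other alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 and upper-quartile size factors or library totals in place of TMM, no expression filter or CPM of at least 1 in 4 libraries, edgeR without robust estimation, removal of 627 immunoglobulin rows, thinning to the smallest total, and leaving out each library or tonsil. The pipeline was tested on simulated counts for the 20192 genes with 200 changed. The edgeR fit recovered 22% of 2-fold and 52% of 4-fold changes with 6 false calls. The blocked fit recovered 4% and 43%, limma-voom 19% and 51%, and DESeq2 51% and 70%. False calls made up 7.5% of edgeR, 7.8% of blocked, 6.7% of limma-voom and 37.9% of DESeq2 calls. The simulated counts held no tonsil effect, so they cannot show what the block gains in paired libraries. They also held far fewer changed genes than the 8211 called in the real libraries. No 2 libraries agreed within sampling noise. The labels name no batch or date, and the tonsil code was the only grouping besides population. A count of 0 in a library allows up to 3 counts, or 0.0323 to 0.0933 CPM, depending on its total.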

Results

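Gene counts were obtained from B cells sorted from 4 human tonsils. From each tonsil, 1 library came from germinal center (GC) B cells and 1 from marginal zone (MZ) B cells, giving 8 libraries and 4 per population. GC B cells are the cells of the follicle that divide, mutate their antibody genes and undergo selection. MZ B cells are largely unswitched, IgM-bearing cells that answer carbohydrate antigens rapidly. The series belongs to work on IgM antibodies in common variable immunodeficiency, an antibody deficiency, and on the blood-cell sugars that such antibodies bind. The design text names a single contrast, GC against MZ B cells of the tonsil, and treatment is given as none. Library totals were 61632942, 79553989, 52262135 and 32143496 counts for the GC libraries of tonsils 1 to 4, and 92812999, 51274648, 61340393 and 54924610 counts for the MZ libraries. At these totals, 1 count corresponded to between 0.0108 and 0.0311 CPM, the count scaled to a library total of 1e6. The MZ columns of the deposited table carry the word effector in place of MZ, and their assignment rests on the tonsil code and on the GC columns being named as such.

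The 2 populations differed in 8211 of 20192 tested genes, or 40.7%, and 18 of 20 listed GC B cell markers were called higher in GC. Transcripts of LMO2, a transcription cofactor of GC B cells, stood at 259 ± 30 CPM in GC and 34.9 ± 4.5 CPM in MZ libraries (SD, n = 4 each), a log2 fold change of 2.89 ± 0.13 (SE, edgeR quasi-likelihood test, adjusted p = 2.2e-05). In the other direction, IGHM, the constant gene of the IgM heavy chain, stood at 2073 ± 1356 CPM in GC and 46408 ± 24380 CPM in MZ libraries. BCL2, which protects cells from apoptosis, stood at 5.59 ± 1.89 CPM in GC and 68.0 ± 14.2 CPM in MZ libraries, a log2 fold change of -3.61 ± 0.27 (edgeR adjusted p = 8.5e-05). Of the called genes, 3979 were higher in GC and 4232 higher in MZ B cells, 6333 were protein-coding, and 8030 changed in the same direction in all 4 tonsils. A change of at least 2-fold was called for 4356 genes, 1441 of them higher in GC and 2915 higher in MZ B cells. The first principal component held 49.0% of the variance and separated the populations, and the second, with 19.5%, set the MZ library of tonsil 2 apart from the other 7. Leaving out both libraries of tonsil 1, 2, 3 or 4 reduced the genes higher in GC from 3979 to 2883, 3215, 2525 or 3115. Those higher in MZ went from 4232 to 3236, 3703, 2951 or 3477.

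The largest increases in GC B cells, among genes past the expression and direction requirements, belonged to TUBB3, a tubulin, at 130 ± 44.9 CPM against 12.6 ± 9.2 CPM in MZ libraries, and to DBNDD1, LMO2, SUGCT, MAML3, FGFR1, ASB13 and KCNMB4. Their log2 fold changes lay between 2.48 for KCNMB4 and 3.37 for TUBB3. MAML3 is a coactivator of Notch signalling, and its log2 fold change was 2.72 ± 0.24. NME1-NME2 is a read-through transcript that shares its exons with 2 single genes, so its value of 3.28 ± 1.02 is uncertain, and its call was lost with tonsil as a block (adjusted p = 0.087) and with no low-count filter (adjusted p = 0.089). It was lost too without GC replicate 2 or 3, any 1 of MZ replicates 1, 3 and 4, or both libraries of tonsil 1, 3 or 4, with adjusted p up to 0.095. The remaining 6 of the 15 genes were near-identical copies of the 5.8S ribosomal RNA gene, among which reads cannot be placed with certainty. Ribosomal RNA had been depleted, so these counts are a remainder and cannot be read as a difference between the cells. Ribosomal RNA genes took 0.136% of counts in the GC library of tonsil 1. They took 0.0161 to 0.0204% in the other GC and 0.0053 to 0.0088% in MZ libraries. All 6 copies were highest in the GC library of tonsil 1. Of these, RNA5-8SN1 stood at 188 CPM in the GC library of tonsil 1 and between 18.7 and 23.4 CPM in the other GC libraries, its log2 fold change went from 2.97 to 1.44 without the former, and its call was lost with limma-voom (adjusted p = 0.0500001).

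The largest increases in MZ libraries were those of APOD, FER1L4, IFI44L, IFI44, SDK2, NR4A2, COL19A1, CTLA4, MMP17, ITM2A, FYB1, PTPRK, IL6, CD28 and TTC39B. Their log2 fold changes lay between -7.94 for APOD and -5.36 for TTC39B. Among these genes, IFI44L and IFI44 are induced by type I interferon. IFI44L stood at 0.31 ± 0.22 CPM in GC and 25.9 ± 11.6 CPM in MZ libraries. COL19A1, a collagen gene, had a log2 fold change of -5.74 ± 0.38, and IL6, a cytokine gene, one of -5.52 ± 0.53. CTLA4 and CD28 encode receptors known from T cells, and CD28 is in the T cell marker list. The mean log2 CPM of that list was between 3.60 and 4.98 in MZ and between -0.60 and 1.06 in GC libraries. T cells may contribute to every gene of this group that they also express, and their part was not measured. The log2 fold change of NR4A2 was -5.83 and became -4.60 without MZ replicate 3, and that of FER1L4 went from -7.09 to -6.16. That of CTLA4 went from -5.74 to -6.60 without GC replicate 4. APOD varied from 1.27 to 43.1 CPM among the MZ libraries, its log2 fold change was -8.87 without GC replicate 2 and -7.23 without MZ replicate 2, and its call was lost with limma-voom (adjusted p = 0.31), as was that of FER1L4 (adjusted p = 0.065).

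Among 20 GC B cell markers, 18 rose in GC B cells, none fell and 2 did not pass the test. BCL6, the repressor that sets the GC program, stood at 583 ± 35.2 CPM against 179 ± 50.9 CPM in MZ libraries. Log2 fold changes were 1.76 for MME (CD10), 2.19 for HTR3A and 1.87 for BCL7A. CD38 rose by less, with a log2 fold change of 0.93 ± 0.28, and its call was lost without GC replicate 2, 3 or 4, without MZ replicate 3, and without tonsil 3 or 4, with adjusted p up to 0.12. The count adjusted over the list alone was 18, and the list as a whole was higher in GC by camera (adjusted p = 5.5e-15 with a preset correlation of 0.01, adjusted p = 0.12 with an estimated correlation). The markers were not absent from MZ libraries, where their mean log2 CPM was 5.86, 6.80, 6.13 and 6.47 in tonsils 1 to 4, against 7.94 to 8.0007 in GC libraries.

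Of 19 marginal zone and memory markers, 10 rose in MZ B cells, 2 rose in GC B cells and 7 did not pass, and adjusted over the list alone the counts were again 10 and 2. TNFRSF13B, which encodes the receptor TACI, stood at 4.49 ± 2.01 CPM in GC and 67.4 ± 22.6 CPM in MZ libraries. CD1C, a lipid-presenting molecule, had a log2 fold change of -2.10, CD44, an adhesion receptor, of -2.71, and ABCB1, an efflux pump of resting B cells, of -4.78. DTX1, a Notch target, went the other way at 1.54 ± 0.12. CR2 (CD21) at -0.19 ± 0.21, CD27 at 0.11 ± 0.27 and PLD4 at -0.26 ± 0.45 did not differ beyond their error. Their signs turned without MZ replicate 1 (0.056, -0.13 and 0.031), and that of CD27 also without GC replicate 2 (-0.010). The list was higher in MZ by camera (adjusted p = 3.0e-06, adjusted p = 0.11 with an estimated correlation), and the call was lost once genes held by other lists were removed (adjusted p = 0.070). Leaving out any 1 library other than GC replicate 4 or MZ replicate 2 left 1 member in place of 2 higher in GC, as did library totals alone or no low-count filter. T cells also express CD44, and T cell markers (22 of 23, median log2 fold change -4.79) and plasma cell markers (12 of 15) rose in the same MZ libraries. All 11 naive B cell markers passed: 8 rose in MZ B cells, among them IGHD at -5.42, PLPP5 at -3.37, YBX3 at -2.88 and FCER2 (CD23) at -2.08, and 3 rose in GC B cells, among them BACH2 at 1.56 and IL4R at 1.42. Adjusted over the list alone these counts were 8 and 3, and camera called the list higher in MZ (adjusted p = 0.0013, adjusted p = 0.12 with an estimated correlation).

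**Figure D1:**
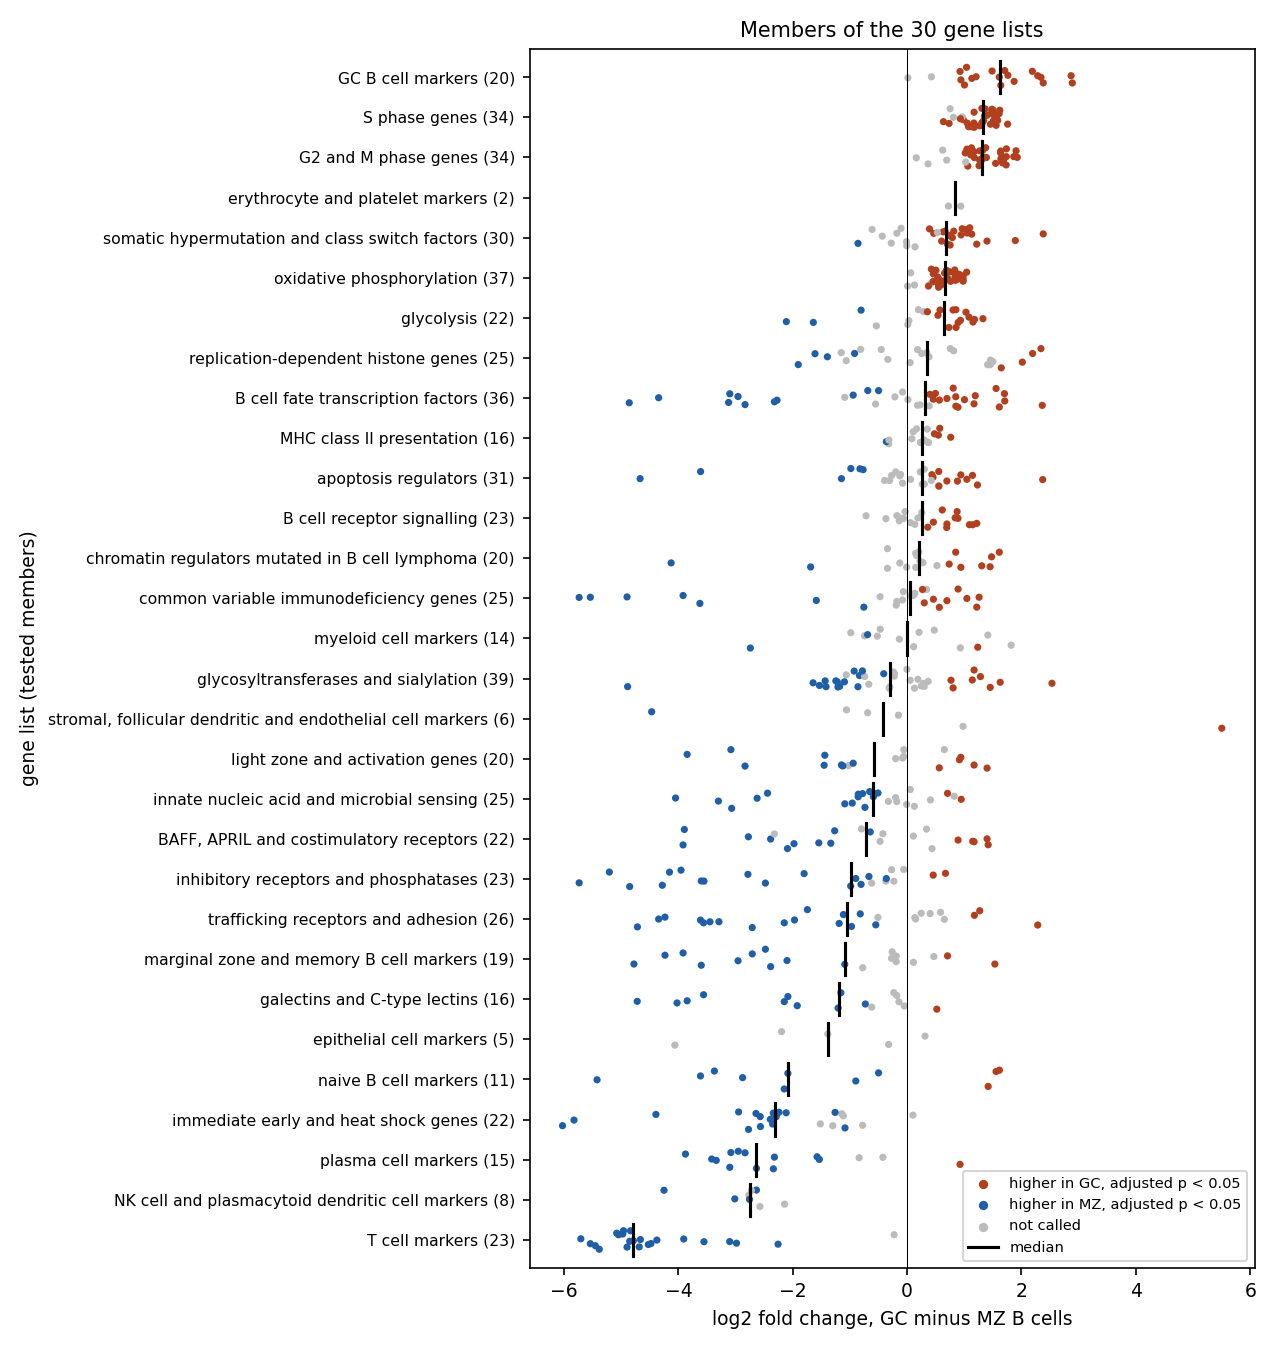
Each point is a tested member of 1 of the 30 gene lists, placed at its log2 fold change (GC minus MZ) and coloured by its edgeR call, with a black bar at the list's median. Medians run from -4.79 for T cell markers to 1.63 for GC B cell markers, and lists such as the common variable immunodeficiency genes hold members on both sides of 0.

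Most genes of cell division were higher in GC B cells. Of 34 S phase genes, 31 rose and 3 did not pass, and of 34 genes of G2 and M phase, 29 rose and 5 did not pass. Without GC replicate 3, 19 genes of G2 and M phase were called, and 15 without both libraries of tonsil 3. MCM2, part of the replicative helicase, stood at 331 ± 38.1 CPM in GC and 109 ± 24.9 CPM in MZ libraries, and E2F1 had a log2 fold change of 1.56. BIRC5 had one of 1.93 and CCNB1, the cyclin of mitotic entry, one of 1.91. MKI67 stood at 503 ± 64.7 CPM in GC and 241 ± 111 CPM in MZ libraries, and its call was lost without GC replicate 2 or 3, without MZ replicate 3, and without tonsil 3 or 4, with adjusted p up to 0.12. Adjusted over the list alone, 32 and 30 genes rose, and camera called S phase genes (adjusted p = 5.5e-15, adjusted p = 0.33 with an estimated correlation) and G2 and M phase genes (adjusted p = 1.3e-10, adjusted p = 0.36 with an estimated correlation). Division transcripts varied among MZ libraries, with a mean log2 CPM of G2 and M phase genes of 4.05 in tonsil 1 and 5.63 in tonsil 2. GC B cell markers were likewise lowest in tonsil 1 (5.86) and highest in tonsil 2 (6.80) among MZ libraries. The variation was thus not one of division genes alone, and its source was not tested. Replication-dependent histone genes divided, 4 higher in GC, 4 higher in MZ and 17 not called of 25 tested, with H3C8 at 2.34 and H2AC6 at -1.90. The 4 higher in GC became 1 without GC replicate 1 and 2 without GC replicate 2 or 3 or without MZ replicate 1, 2 or 4. They were 7 with DESeq2, and 2 with no low-count filter or a CPM of at least 1 in 4 libraries. Adjusted over the list alone the histone counts were 2 and 4, and camera made no call (adjusted p = 0.73).

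Factors of somatic hypermutation and class switching, the GC reactions that edit antibody genes, followed the same direction. Of 30 tested, 20 rose in GC B cells, 1 rose in MZ B cells and 9 did not pass, and adjusted over the list alone the counts were 20 and 2. Without MZ replicate 3 or 4, with DESeq2, with a CPM of at least 1 in 4 libraries and with all libraries thinned to the smallest total, 2 members were higher in MZ. HMCES, which shields abasic sites in DNA, stood at 774 ± 88.0 CPM in GC and 208 ± 61.9 CPM in MZ libraries. UNG, a uracil glycosylase, stood at 80.9 ± 10.1 CPM in GC and 30.7 ± 7.5 CPM in MZ libraries, and RPA1, a single-strand DNA binding protein, had a log2 fold change of 1.04 ± 0.11. The list was called higher in GC (camera adjusted p = 7.3e-06, adjusted p = 0.33 with an estimated correlation). Several of these factors are also used in ordinary replication and repair.

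B cell receptor signalling genes rose in GC B cells in 11 of 23 cases, with none falling and 12 not passing. CD79B, a signalling chain of the receptor, had a log2 fold change of 1.09 ± 0.12 and the kinase SYK one of 0.84 ± 0.11. Adjusted over the list alone the count was again 11, and camera called the list (adjusted p = 0.0074, adjusted p = 0.35 with an estimated correlation). With tonsil as a block, with a CPM of at least 1 in 4 libraries, and without GC replicate 4 or MZ replicate 2 or 3, 1 member was called higher in MZ. Inhibitory receptors and phosphatases, which damp that signal, moved the other way: 16 of 23 rose in MZ B cells, 2 rose in GC B cells and 5 did not pass, and 17 and 2 adjusted over the list alone. LAIR1, a collagen receptor, stood at 1.54 ± 1.0 CPM in GC and 55.6 ± 14.1 CPM in MZ libraries, FCGR2B had a log2 fold change of -1.80 and FCRL5 of -2.48. The list was called higher in MZ (camera adjusted p = 2.1e-09, adjusted p = 0.19 with an estimated correlation). Its members CD5, PDCD1 and CTLA4 are also T cell genes, and T cell markers were higher in the same MZ libraries by a median log2 fold change of -4.79.

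Receptors of cell movement and adhesion were mostly higher in MZ B cells: 16 of 26 rose there, 3 rose in GC B cells and 7 did not pass. S1PR1, which draws lymphocytes toward blood and lymph, stood at 2.15 ± 0.82 CPM in GC and 56.1 ± 23.5 CPM in MZ libraries, whereas S1PR2, which holds cells in the GC, stood at 248 ± 39.6 and 51.0 ± 14.6 CPM. CD44 had a log2 fold change of -2.71, while CXCR4 at -0.51 ± 0.34 was not called. CXCR4 was called without MZ replicate 2 (-0.78, adjusted p = 0.014) and without both libraries of tonsil 2 (adjusted p = 0.040), and was at -0.25 without MZ replicate 3. Adjusted over the list alone, 16 rose in MZ and 5 in GC, and camera called the list higher in MZ (adjusted p = 1.6e-04, adjusted p = 0.12 with an estimated correlation). The members higher in GC numbered 6 with tonsil as a block and 5 without MZ replicate 3, in place of 3. T cells share S1PR1 and CD44, and their markers were higher in the same MZ libraries.

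Sensors of microbes and nucleic acids rose in MZ B cells in 15 of 25 cases, rose in GC B cells in 2 and did not pass in 8, with the same counts adjusted over the list alone. TLR7, a receptor for single-stranded RNA, stood at 2.45 ± 0.52 CPM in GC and 20.6 ± 3.5 CPM in MZ libraries. NOD2 had a log2 fold change of -2.44 and STING1 of -4.05, whereas TLR9, the receptor for unmethylated CpG DNA, was not called at 0.41 ± 0.19. Without GC replicate 1, 2 or 3 or MZ replicate 3 or 4, with library totals alone and with no low-count filter, 1 member in place of 2 was higher in GC. The list was called higher in MZ (camera adjusted p = 0.0045, adjusted p = 0.35 with an estimated correlation). Genes listed with galectins and C-type lectins rose in MZ B cells in 10 of 16 cases, with 1 higher in GC and 5 not called. Adjusted over the list alone the counts were 11 and 1. CLEC2B had a log2 fold change of -4.02 and CD69, an early activation marker, of -3.85. SELPLG, a listed gene that encodes a ligand of selectins and not a lectin, had one of -3.56. Camera called the list higher in MZ (adjusted p = 5.2e-05, adjusted p = 0.12 with an estimated correlation). Without GC replicate 4, STING1 was at -4.68 and CLEC2B at -4.65. STING1, SELPLG and CD69 are expressed by T cells too, whose markers were higher in these libraries. Of 8 tested natural killer and plasmacytoid dendritic cell markers, 4 also rose in the MZ libraries and 4 did not pass. LILRA4 had a log2 fold change of -4.25 and IL3RA of -2.76. Whether plasmacytoid dendritic cells contributed to the TLR7 values was not tested.

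Glycosyltransferases and sialylation enzymes, which build the sugars of the cell surface, went both ways. Of 39 tested, 8 rose in GC B cells, 15 rose in MZ B cells and 16 did not pass, and adjusted over the list alone the counts were 9 and 16. GCNT2, which makes the branched I antigen also found on red cells, stood at 25.5 ± 3.5 CPM in GC and 11.6 ± 1.5 CPM in MZ libraries. B4GALT5 had a log2 fold change of 1.63, ST3GAL5 of -1.64, FUT8, the core fucosyltransferase, of -1.43 and ST3GAL1 of -1.42. ST6GAL1, which makes the sialylated ligand of CD22, was not called at 0.37 ± 0.16, though it was without MZ replicate 4 (0.52, adjusted p = 0.021). Camera made no call for the list (adjusted p = 0.24). In the same MZ libraries, T cell markers (22 of 23) and plasma cell markers (12 of 15) rose. Whether such cells contributed to the values of these enzymes was not tested.

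Receptors for BAFF, APRIL and costimulation divided in a similar way: 10 of 22 rose in MZ B cells, 5 rose in GC B cells and 7 did not pass, or 11 and 5 adjusted over the list alone. CD40 had a log2 fold change of 1.17 and IL4R of 1.42, against -3.92 for TNFRSF13B, and camera made no call (adjusted p = 0.18). Light zone and activation genes also divided, 5 higher in GC, 8 higher in MZ and 7 not called of 20, with 6 and 9 adjusted over the list alone. CD86, a costimulatory ligand, stood at 74.1 ± 9.5 CPM in GC and 28.1 ± 3.2 CPM in MZ libraries, IRF4 had a log2 fold change of -2.83 and CD69 of -3.85, and camera made no call (adjusted p = 0.26). Leaving out MZ replicate 1 (adjusted p = 0.029) or both libraries of tonsil 1 (adjusted p = 0.025) brought a call in the MZ direction. IRF4 is also in the plasma cell list, and T cells express CD69. Plasma cell markers (12 of 15) and T cell markers (22 of 23) rose in the same MZ libraries.

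Of 25 genes mutated in common variable immunodeficiency, 9 rose in GC B cells, 7 rose in MZ B cells and 9 did not pass, with the same counts adjusted over the list alone. NFKB1 had a log2 fold change of 1.05, TNFRSF13B of -3.92 and TNFSF12, which encodes TWEAK, of -3.62, while CR2 and CD27 were among those not called. The list's median was 0.05 and its mean -0.79, and camera, whose direction was MZ, made no call (adjusted p = 0.73). Its members CTLA4, ICOS and IL21 are T cell genes.

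Regulators of apoptosis did not move as a list: 11 of 31 rose in GC B cells, 6 rose in MZ B cells and 14 did not pass, with the same counts adjusted over the list alone. Without GC replicate 2, 7 were called higher in GC. BCL2 at -3.61 and CASP10 at -4.67 were among those higher in MZ (camera adjusted p = 0.73), and the median of 0.26 and the mean of -0.03 differed in sign. B cell fate transcription factors were called in 28 of 36 cases, 17 higher in GC and 11 higher in MZ, as they were adjusted over the list alone. IRF8 had a log2 fold change of 1.19 and BACH2 of 1.56, against -2.27 for ZEB2 and -4.86 for KLF3, a factor of resting lymphocytes. The median was 0.31 and the mean -0.30, with no camera call (adjusted p = 0.40). Chromatin regulators mutated in B cell lymphoma rose in GC B cells in 7 of 20 cases and in MZ B cells in 2, with 11 not called, or 8 and 2 adjusted over the list alone. DNMT1, the maintenance DNA methyltransferase, stood at 739 ± 55.7 CPM in GC and 270 ± 54.7 CPM in MZ libraries, whereas DNMT3A, a de novo methyltransferase, stood at 3.65 ± 1.29 and 63.4 ± 13.3 CPM, and TET2 had a log2 fold change of -1.69 (camera adjusted p = 0.21).

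Most tested genes of oxidative phosphorylation and glycolysis were higher in GC B cells. Of 37 genes of oxidative phosphorylation, 33 rose and 4 did not pass, and 34 rose adjusted over the list alone. ATP5F1B had a log2 fold change of 0.89 and SDHC of 0.98 (camera adjusted p = 4.4e-10, adjusted p = 0.33 with an estimated correlation). Of 22 glycolysis genes, 14 rose in GC B cells, 3 rose in MZ B cells and 5 did not pass, or 15 and 3 adjusted over the list alone. GAPDH stood at 4004 ± 384 CPM in GC and 1597 ± 371 CPM in MZ libraries and LDHA had a log2 fold change of 1.03 (camera adjusted p = 0.0030, adjusted p = 0.36 with an estimated correlation). Counts on the mitochondrial chromosome took 3.12, 3.16, 3.13 and 3.50% of GC and 5.90, 5.50, 2.85 and 4.47% of MZ libraries of tonsils 1 to 4, higher in MZ in all but tonsil 3. MHC class II presentation genes were mostly not called, with 4 of 16 higher in GC, 1 higher in MZ and 11 not called, the same adjusted over the list alone (camera adjusted p = 0.31). IFI30, a lysosomal reductase, had a log2 fold change of 0.76, with its call lost without tonsil 2 (adjusted p = 0.061), and HLA-DOA one of 0.55, with its call lost with library totals alone (adjusted p = 0.053), without GC replicate 1 or 4, without MZ replicate 2, 3 or 4, and without tonsil 2, 3 or 4 (adjusted p up to 0.11). With library totals alone 2 and 0 members were called, with no low-count filter 2 and 1, with tonsil as a block 6 and 0, and without MZ replicate 3 only 1 and 0. Those higher in GC numbered 1 without GC replicate 1 or MZ replicate 2 or 4, and 2 without GC replicate 2 or 4. The 1 higher in MZ was lost without GC replicate 1, 2 or 3 or MZ replicate 1.

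Immediate early and heat shock genes, which respond within minutes to stimulation or stress, were higher in MZ B cells. Of 22 tested, 16 rose, none fell and 6 did not pass, and 20 rose adjusted over the list alone. FOS stood at 582 ± 129 CPM in GC and 3052 ± 1852 CPM in MZ libraries, and JUN, KLF6 and NR4A2 had log2 fold changes of -2.56, -2.35 and -5.83. Without MZ replicate 3 these were -1.92, -1.86 and -4.60, and NR4A2 stood at 104 CPM in that library against 5.04 to 30.7 CPM in the other MZ libraries. The list was called higher in MZ by camera (adjusted p = 1.5e-05, adjusted p = 0.43 with an estimated correlation). The list's mean log2 CPM was 8.46, 7.32, 10.23 and 8.78 in the MZ libraries of tonsils 1 to 4 and between 6.55 and 6.89 in the GC libraries, so the MZ libraries spread far more widely. Without MZ replicate 3, 12 members were called. T cell markers (22 of 23) and plasma cell markers (12 of 15) rose in the same MZ libraries.

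Transcripts of other cell types were examined because a sorted population can carry them. Of 23 tested T cell markers, 22 rose in MZ libraries and 1 did not pass, with the same count adjusted over the list alone. CD6 stood at 2.56 ± 1.35 CPM in GC and 85.2 ± 30.7 CPM in MZ libraries, and SH2D1A had a log2 fold change of -4.53 (camera adjusted p = 5.2e-20, adjusted p = 0.19 with an estimated correlation). Counts on the variable segments of the T cell receptor alpha and beta genes summed to between 29.7 and 106 CPM in MZ and between 2.14 and 5.85 CPM in GC libraries. Plasma cell markers rose in MZ libraries in 12 of 15 cases, with CD38 higher in GC and 2 not called, the same adjusted over the list alone. CD38 was not called without GC replicate 2, 3 or 4 or MZ replicate 3, with adjusted p from 0.054 to 0.065. FKBP11 had a log2 fold change of -3.34, DERL3 of -3.42 and SLAMF7 of -3.08 (camera adjusted p = 2.3e-06, adjusted p = 0.35 with an estimated correlation). Of 8 tested natural killer and plasmacytoid dendritic cell markers, 4 rose in MZ libraries and 4 did not pass, or 5 adjusted over the list alone and 7 of 11 tested with DESeq2, with LILRA4 at -4.25 (-5.12 without GC replicate 4) and IL3RA at -2.76 (camera adjusted p = 0.012, adjusted p = 0.35 with an estimated correlation).

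Markers of the remaining cell types showed no call as lists. Of 14 myeloid markers, 1 rose in GC, 2 rose in MZ and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.77). MPEG1, which B cells also express, had a log2 fold change of -2.74 and AIF1 one of 1.24, whose call was lost without tonsil 3 (adjusted p = 0.055) or tonsil 4 (adjusted p = 0.075). With tonsil as a block, the myeloid counts were 2 and 1, and without GC replicate 2 or MZ replicate 3 or 4 they were 2 and 2. They were 1 and 1 without GC replicate 1, 3 or 4, 2 and 1 without MZ replicate 1, and 3 and 1 without MZ replicate 2. They were 4 and 2 with DESeq2, 3 and 2 with no low-count filter and 1 and 1 with library totals alone. Stromal, follicular dendritic and endothelial markers gave 1 higher in GC, 1 higher in MZ and 4 not called of 6, the same adjusted over the list alone and 2 and 1 with tonsil as a block, DESeq2 or library totals alone, against 0 and 1 with a CPM of at least 1 in 4 libraries (camera adjusted p = 0.80, with a median of -0.42 and a mean of 0.02). CXCL13, a chemokine that follicular helper T cells also make, stood at 0.38 ± 0.18 CPM in GC and 8.17 ± 6.68 CPM in MZ libraries, a log2 fold change of -4.47 that was -3.73 without MZ replicate 4, and DCN, a matrix proteoglycan, at 1.06 ± 0.98 and 0.024 ± 0.048 CPM, with its call lost without tonsil 3 (adjusted p = 0.054). Epithelial markers (5 tested) and erythrocyte and platelet markers (2 tested) held no called gene, in both cases also adjusted over the list alone (camera adjusted p = 0.78 and 0.92).

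**Figure D2:**
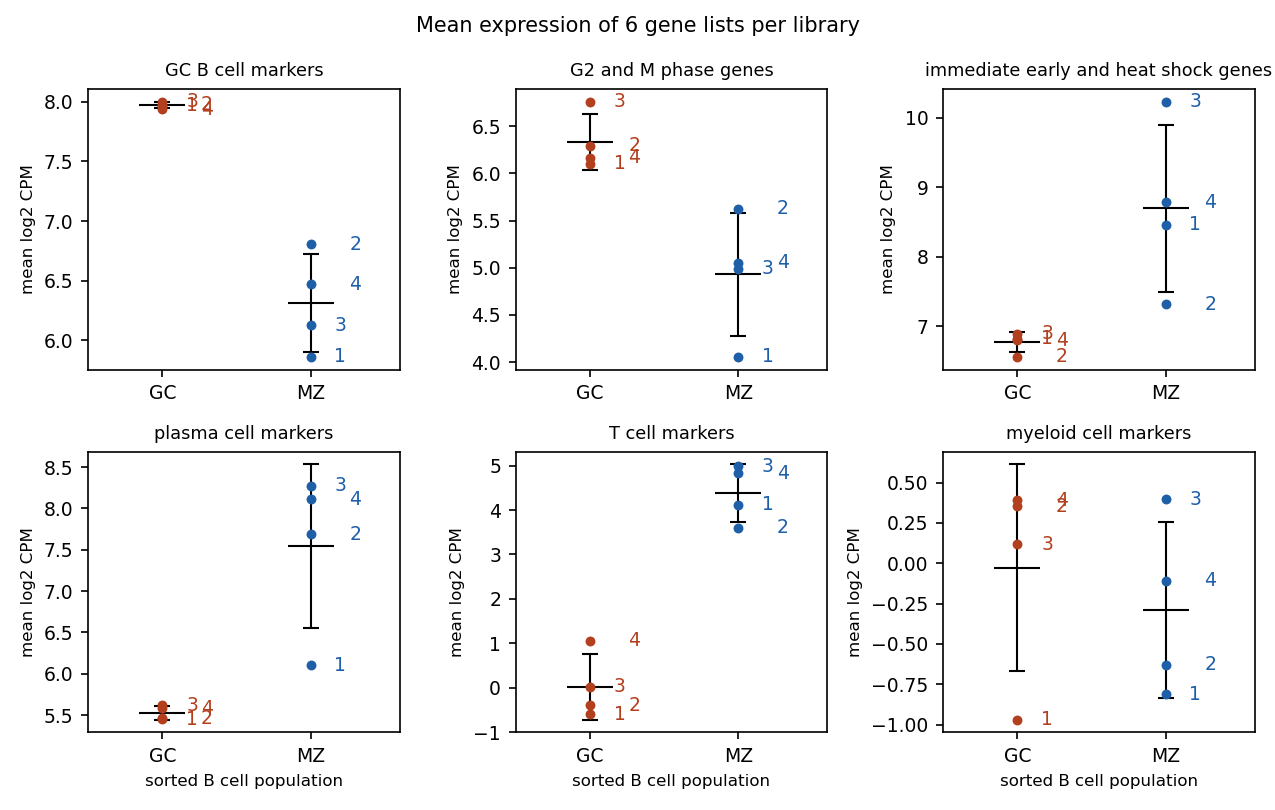
Mean log2 CPM of the tested members of 6 gene lists in each library, with the tonsil number beside each point and the mean ± SD of the 4 libraries of a population in black. T cell markers lie between -0.60 and 1.06 in GC libraries and between 3.60 and 4.98 in MZ libraries, while myeloid markers overlap.

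Immunoglobulin genes took 1.69 ± 0.12% of all counts in GC libraries and 14.3 ± 9.5% in MZ libraries (SD, n = 4 each; exact two-sided permutation test, p = 0.029, the smallest that 4 against 4 can give), higher in MZ in 4 of 4 tonsils. The MZ shares were 4.25, 10.3, 26.6 and 16.1% in tonsils 1 to 4. Within tonsil pairs the exact sign-flip test gave p = 0.125, the smallest that 4 pairs allow. Plasma cell markers rose in the same MZ libraries. Among heavy-chain constant counts, IGHM made up 21.7 ± 13.1% in GC and 71.9 ± 22.9% in MZ libraries, and IGHD 1.28 ± 0.61% and 8.29 ± 5.17%, both higher in MZ in 4 of 4 tonsils. IGHG1 made up 28.5 ± 5.6% in GC and 8.06 ± 11.2% in MZ libraries, IGHG3 22.9 ± 10.4% and 5.79 ± 8.42%, and IGHA1 8.36 ± 6.15% and 0.99 ± 0.11%, each higher in GC in 4 of 4 tonsils. IGHG2, IGHG4, IGHA2 and IGHE shares were also higher in GC in 4 of 4 tonsils. As a share of library totals the direction of the means turned for IGHG1 (-0.605 points, GC minus MZ), IGHG2 (-0.231), IGHG3 (-0.420), IGHG4 (-0.111) and IGHA2 (-0.00422), with IgG constant genes at 72737 CPM in the MZ and 7759 CPM in the GC library of tonsil 3, and no isotype passed in that form. The difference in IGHD share went from -7.01 to -4.65 points without MZ replicate 2, and those of IGHA1 and IGHA2 from 7.36 to 4.82 and from 1.17 to 0.646 points without GC replicate 2. By exact two-sided permutation tests the unadjusted p was 0.029 for IGHD, IGHG4, IGHA1 and IGHA2, and after Benjamini-Hochberg adjustment over 9 isotypes none passed, with adjusted p from 0.064 to 0.086. The IgG genes are close paralogs whose reads can be split, so their separate shares are less certain than their sum, which was 67.2 ± 16.7% in GC and 18.5 ± 25.8% in MZ libraries. The MZ library of tonsil 3 held 57.1% IgG and the other MZ libraries between 3.19 and 7.27%.

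**Figure D3:**
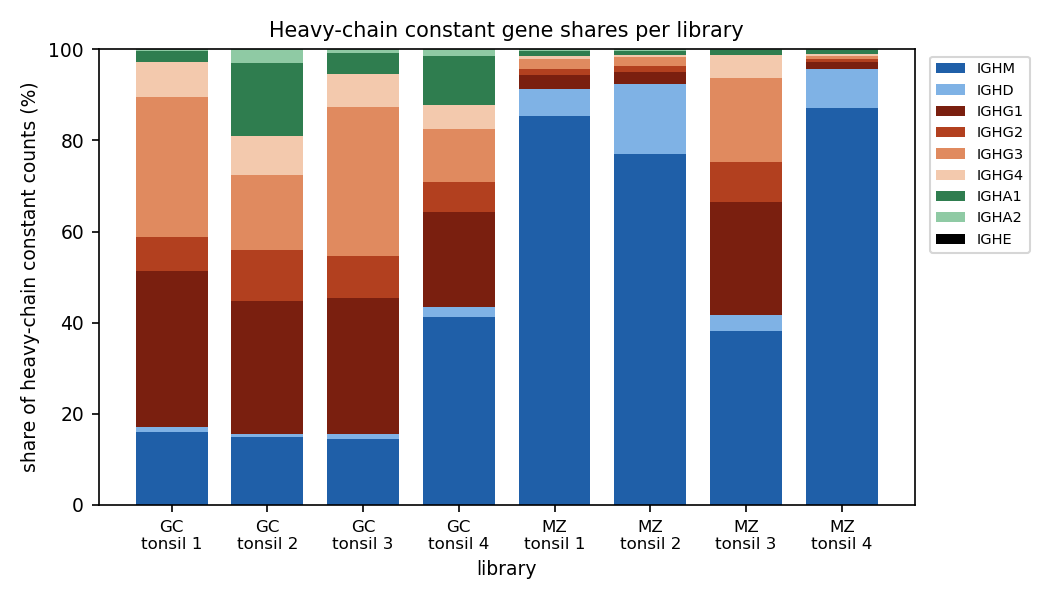
Stacked bars give the share (percent) of each heavy-chain constant gene in the sum of heavy-chain constant counts of each library. IGHM is the largest part in all 4 MZ libraries (38.3% in tonsil 3, at least 76.9% in the others) and reaches 41.3% in the GC library of tonsil 4.

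The variable gene IGHV4-34, located on chromosome 14 at 106373663 to 106374145 (hg38), encodes antibodies that bind the I and i sugars of red cells. Its counts made up 3.98 ± 2.09% of the counts on 48 IGHV genes in GC libraries and 10.2 ± 5.8% in MZ libraries, higher in MZ in 4 of 4 tonsils (exact two-sided permutation test, p = 0.086, adjusted p = 0.34 over 8 shares). Without MZ replicate 4 the difference went from -6.22 to -3.63 points. Per tonsil the shares were 4.51% (95% Wilson interval 4.34 to 4.69) in GC and 10.6% (10.5 to 10.8) in MZ for tonsil 1, 2.43% (2.30 to 2.55) and 7.99% (7.91 to 8.08) for tonsil 2, 2.27% (2.14 to 2.40) and 4.19% (4.15 to 4.22) for tonsil 3, and 6.71% (6.47 to 6.96) and 18.0% (17.9 to 18.1) for tonsil 4. These intervals cover counting error only, since reads of a B cell clone are not independent molecules. Within each population, the libraries took the same order by IGHV4-34 share as by IGHM share of heavy-chain constant counts. The MZ library of tonsil 3, with 38.3% IGHM, had the lowest IGHV4-34 share of the MZ libraries. A difference in isotype composition therefore cannot be told apart from one between the populations. Plasma cell markers (12 of 15) also rose in the MZ libraries. The whole IGHV4 family made up 19.5 ± 1.9% in GC and 25.5 ± 4.6% in MZ libraries (adjusted p = 0.34 by the same exact test), higher in MZ in 4 of 4 tonsils. IGHV1 made up 18.7 ± 4.2% and 13.5 ± 4.9% (adjusted p = 0.61, exact), a difference of 5.15 points that was 3.07 without GC replicate 1 and turned to -0.125 as a share of library totals (exact adjusted p = 0.0327, a value shared by IGHV4-34, IGHV3 and IGHV4 in that form, all higher in MZ), and IGHV3 48.3 ± 3.9% and 48.5 ± 5.6% (adjusted p = 0.94, exact), whose direction turned without GC replicate 1 (1.42 points) or MZ replicate 2 (1.68) or 3 (1.10). Shares of library totals also carry the larger immunoglobulin part of MZ libraries, so they do not measure use among IGHV genes. The same holds for CPM values of IGHV4-34 itself, which rose in MZ libraries with a log2 fold change of -4.67 ± 0.73. This fold change was -4.01 without MZ replicate 4.

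**Figure D4:**
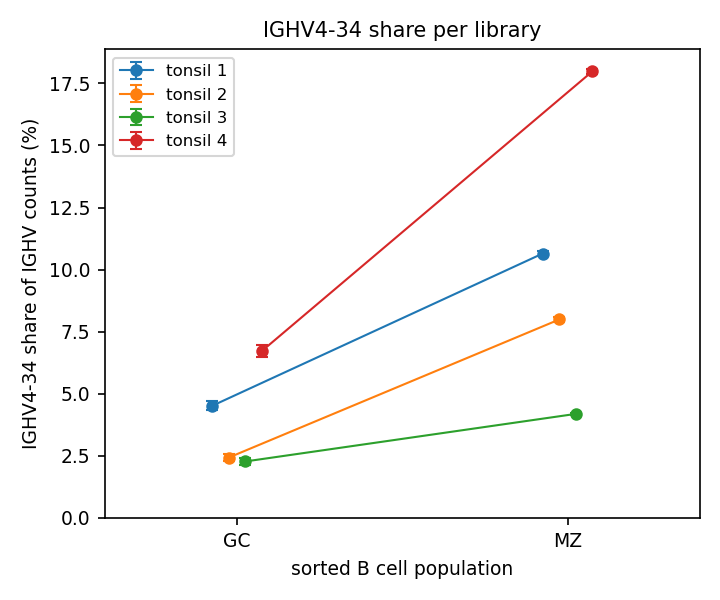
Share of IGHV4-34 in all IGHV counts (percent) in the GC and MZ library of each tonsil, joined by a line, with 95% Wilson intervals that cover counting error only. All 4 lines rise from GC to MZ, from 2.27 to 6.71% in GC and from 4.19 to 18.0% in MZ libraries.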

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

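Thinning to the smallest total was an alternative set before the data were examined, and the other tests weighed in this part were chosen only after the result was seen. Of 306 groups of 4 libraries, 20 held a library far from the other 3 by Dixon's 95% criterion, where chance gives about 1 in 20. Of these, 7 were in the GC library of tonsil 4 and 5 in the MZ library of tonsil 3.

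In GC libraries, RNA5-8SN1 stood at 188 CPM in tonsil 1 (others 18.7 to 23.4), CCNB1 at 181 CPM in tonsil 3 (120 to 127) and IL4R at 690 CPM in tonsil 3 (849 to 872). In the GC library of tonsil 4, MMP17 stood at 0.852 CPM (0.283 to 0.335), TNFRSF13B at 7.495 CPM (3.31 to 3.73), STING1 at 0.999 CPM (0.283 to 0.316), CD6 at 4.59 CPM (1.82 to 1.93) and IGHM at 4103 CPM (1304 to 1503). There the IGHM share was 41.3% (14.5 to 15.97) and the mean log2 CPM of marginal zone and memory markers 4.93 (4.57 to 4.59). The mean log2 CPM of erythrocyte and platelet markers was 0.70 in the GC library of tonsil 2 (-3.01 to -2.50), and the IGHV1 family share was 24.9% in that of tonsil 1 (15.9 to 17.1).

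In MZ libraries, RNA5-8SN1 stood at 5.37 CPM in tonsil 2 (others 8.76 to 9.18), ABCB1 at 7.90 CPM in tonsil 4 (13.9 to 14.3), CD44 at 430 CPM in tonsil 1 (271 to 288) and TLR9 at 38.1 CPM in tonsil 3 (55.6 to 59.4). In the MZ library of tonsil 3, the shares were 24.9% for IGHG1 (1.49 to 3.09), 8.70% for IGHG2 (0.622 to 1.45), 18.4% for IGHG3 (0.742 to 2.10) and 5.08% for IGHG4 (0.335 to 0.633).

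T cell markers were higher in all 4 MZ libraries. With every library thinned to the smallest total, 22 of 23 markers were called. The fit already scales by library totals, so thinning shows only that these calls did not need the larger totals. Variable segments of the T cell receptor genes, which are in no list and which B cells do not rearrange, were higher in MZ by at least 12.6-fold in every tonsil, which argues against transcription of the markers by MZ B cells alone. T cells among the sorted MZ cells may therefore contribute, a hypothesis found and tested on the same data, and the gates of the sort are not given in the sources used here.

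The MZ library of tonsil 3 held IGHG1 at 37650 CPM, against 639 to 1327 CPM in the other MZ libraries. GC B cells carried over from the same tonsil could not bring this much, since IgG constant counts were 9.37 times those of its GC library. The mean log2 CPM of GC markers was 6.13, below the 7.94 to 8.0007 of GC libraries, which argues against exchanged labels. IgG plasma cells stay open, since plasma cell markers stood at 8.27 against 6.11 to 8.11 in the other MZ libraries, too close to decide. No other explanation was tested.

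Immediate early and heat shock genes were higher in MZ B cells. Without MZ replicate 3, 12 of the 22 members were called, so that library alone does not account for the pattern. After thinning 16 were called, which shows only that the calls did not need the larger totals. T cell markers (22 of 23) and plasma cell markers (12 of 15) rose in the same MZ libraries. The median log2 fold change was -1.82 over 6 heat shock members (SD 1.11) and -2.35 over 16 immediate early members. A response to handling or sorting could raise both sets, and it cannot be told apart from a difference between the cell types, because each population was sorted as its own sample.

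Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called as many as 8211 genes. The highest other split called 14. Every other split mixes GC and MZ libraries within its groups, which widens their spread, so few calls were bound to follow. These counts therefore cannot exclude chance. The tonsils pair the libraries, and 8 of these splits part the 2 libraries of every tonsil, as the real one does. Of those 8, 1, the real one, called as many, and the highest other called 0 genes by edgeR, but 8 splits are too few for a share under 0.05, the smallest being 0.125. The other 27 splits keep both libraries of at least 1 tonsil together.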

How the results depend on the processing

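The member calls without MZ replicate 3 were chosen after seeing the data; the other alternatives were set before. Called genes numbered 5476 (without tonsil 3) to 9004 (without MZ replicate 2), with 9751 by DESeq2, 8564 by limma-voom and 7390 with tonsil as a block (6949 shared with the 8211), and no call changed sign in any of these. Genes higher in GC ranged from 2525 to 4243 over the left-out libraries and tonsils. Of 110 named genes, 10 lost a call somewhere and 1 with the block. No list kept its call with an estimated correlation: adjusted p was 0.11 for marginal zone and memory, 0.12 for GC, naive, trafficking and lectin lists (0.123, 0.124, 0.123 and 0.123), 0.186 for inhibitory receptors and T cells, 0.326 for somatic hypermutation, S phase and oxidative phosphorylation, 0.352 for innate sensing, B cell receptor, plasma cell and natural killer lists, 0.358 for G2 and M phase and glycolysis, and 0.429 for immediate early genes. The cause was not tested.

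By fry, calls appeared for BAFF receptors (0.0179), glycosyltransferases (0.00711), fate factors (0.00627) and chromatin regulators (0.00103), and that of immediate early genes was lost (0.0504); fry does not compare a list with other genes. Without a count filter, light zone genes (0.0392), glycosyltransferases (0.0392) and BAFF receptors (0.0166) were called, with more genes tested. With shared genes removed, the marginal zone list lost its call (0.0701) and BAFF receptors gained one (0.000493). Uncalled lists turned direction: myeloid with DESeq2 (0.836), no filter (0.961) and the block (0.994), apoptosis with no filter (0.961), erythrocyte and platelet with the block (0.994), and common variable immunodeficiency with limma-voom (0.894). By camera the block changed no list's call, and by fry with the block calls appeared for light zone (0.0417), apoptosis (0.0417), MHC class II and common variable immunodeficiency (0.00883 each) and immediate early genes (0.0327). The cause was not tested.

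As a share of library totals, GC minus MZ turned to -0.605 points for IGHG1, -0.231 for IGHG2, -0.420 for IGHG3, -0.111 for IGHG4, -0.00422 for IGHA2 and -0.125 for the IGHV1 family, and IGHV4-34 was -0.0916. IGHV4-34 and the IGHV1, IGHV3 and IGHV4 families each had an adjusted p of 0.0327 by the exact unpaired test in that form, higher in MZ, and no isotype passed. For IgG the MZ library of tonsil 3 turned the means: IgG constant genes stood at 7354, 5791 and 4664 CPM in GC and 1627, 3295 and 2572 CPM in MZ libraries of tonsils 1, 2 and 4, and at 7759 and 72737 CPM in tonsil 3. All IGHV counts together numbered 39618 to 58782 in GC and 294849 to 1282747 in MZ libraries. Shares of library totals carry that difference and do not measure use among IGHV genes. For IGHA2 the cause was not tested. The immunoglobulin share differed by -12.6 points, with p = 0.125 by the exact sign-flip test within tonsil pairs (replicate block), the smallest 4 pairs give, and by -16.0 to -8.52 points over left-out libraries (exact p = 0.0571 each, the smallest 3 against 4 give). Over left-out libraries and tonsils, log2 fold changes ran from -0.13 to 0.38 for CD27, -0.31 to 0.056 for CR2 and -0.74 to 0.031 for PLD4, and the IGHV3 difference from -1.93 to 1.68 points. List adjusted p ran from 0.0251 to 0.495 for light zone, 0.277 to 0.948 for histones, 0.727 to 0.990 for myeloid, 0.698 to 0.983 for epithelial and 0.590 to 0.930 for erythrocyte and platelet lists. Depth limits low genes: 3 counts were 0.0323 to 0.0933 CPM.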

Other observations

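The lists and tests in this part were chosen only after values were seen. Genes induced by interferon were higher in MZ B cells beyond IFI44L, IFI44 and SAMD9L (log2 fold change -4.37), which drew attention first and were left out of the list. Of 32 further members tested, 28 rose in MZ B cells and 1 in GC B cells, with a median log2 fold change of -1.87. GBP2 had a log2 fold change of -4.77, XAF1 of -3.84, DDX60 of -3.71 and IFIT1 of -3.70, while CMPK2 went the other way at 1.62, and ISG15, RSAD2 and MX1 were not called. Camera gave the list an adjusted p of 7.2e-18 over the 2 lists of this part. With an estimated correlation its adjusted p was 0.021, and the unadjusted value was 0.0103. These values come from the libraries in which the pattern was first seen, so they cannot test it independently. The fixed lists were adjusted over more lists. Among them, only marginal zone and memory markers (0.0036) and lectins (0.0085) had smaller unadjusted camera p with an estimated correlation. Neither was called after adjustment (adjusted p = 0.11 and 0.12). T cell markers were higher in the same libraries, and T cells may contribute to genes that they also express.

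Enzymes that build blood group sugars did not move as a group by camera across the tested genes (adjusted p = 0.291, adjusted p = 0.34 with an estimated correlation). Of 6 members, 2 were higher in GC, A4GALT and GCNT2, and 1 was higher in MZ, ST3GAL1. With tonsil as a block, B3GALNT1 was also called higher in GC (log2 fold change 1.02, edgeR adjusted p = 0.035, against 0.085 without the block).

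A4GALT, which makes the glycolipid CD77 of GC B cells, stood at 88.4 ± 12.7 CPM in GC and 21.4 ± 6.8 CPM in MZ libraries (SD, n = 4 each), with an edgeR log2 fold change of 2.05 ± 0.24 (adjusted p = 4.2e-04). Lambda light chains made up 36.0 ± 8.3% of light-chain constant counts in GC and 40.6 ± 11.3% in MZ libraries (exact two-sided permutation test, p = 0.57), higher in MZ in 3 of 4 tonsils.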
